A study of Zea mays with 2 samples.

How the data were processed

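The 2 samples were polyadenylated RNA of the L1 and the L2 layer of the B73 shoot apical meristem, per the labels. Per the labels' protocols, seedlings grew under 15 hours of light at 25 °C and 9 hours of dark at 20 °C. Tissue was captured by laser into mineral oil. RNA was purified with a column kit and treated with DNase, and about 1 ng per layer was amplified with a linear amplification kit. Such amplification starts at the poly(A) tail and shortens products towards the 3′ end, so the last bases of each gene model were also examined alone. Samples were grouped by the layer in their titles.

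The authors deposited the filtered gene set of the maize genome project, release 4a.53, as the sequences used for both samples, per the series description. Each sequence had a description line with the identifier, chromosome, start, end and strand of the gene model, per the file headers. Coordinates are given as in those lines, counted from 1, and the genome build is not given in the sources used here. The reads were aligned with Novoalign, per the submitters' processing notes, and its version, its settings and the read length are not given in the sources used here. The file held no value of any sample, so no level, depth or precision per sample is given, and no test between layers was made. With 1 library per layer no such test would have been possible. The other deposited file was a description of the sequences and was not used for any number.

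Sequences with plus and minus strands began with ATG in 20.2% and 19.4% of cases and ended in a stop codon in 20.6% and 20.7%, so they were read in coding orientation. All 32540 lengths equalled the coordinate span. Because the sequences held introns, a read over an exon junction has no contiguous match in them, and no window of this kind was counted. Intron windows were counted, although reads of messenger RNA fall mostly on exons. Sequence outside the gene models was not searched, so a window called unique here may occur elsewhere in the genome. The set held 1289 ambiguous bases in 25 gene models, and windows with such a base were left out.

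All exact windows of 32 bases were counted with Python 3.11.15 and numpy 2.4.6, with a window and its reverse complement as the same. A window was unique if it occurred at 1 position of the set. Mismatches, which aligners allow, were not considered. Shared windows of 2 gene models were distinct windows found in both, and the closest partner was the gene model with most of them, if at least 100 (the first in file order on a tie). Neighbouring copies were those within 200 kb. Random pairing kept the number of partner genes of each chromosome and used 10000 permutations. Intervals of shares are 95% Wilson intervals (statsmodels 0.14.6) and treat gene models as independent, which related genes are not. The counter was tested on 1700 simulated sequences with 200 planted copies. It differed from a brute-force count in 0 values, and the source of all 200 copies was found as closest partner. The other sequences were random and unrelated, so this tests the counting and not the choice of partner within gene families.

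Gene symbols were taken from a RefSeq gene table of the B73 assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. It paired 16303 gene models (50.1%) with a RefSeq gene. The 10 gene lists held 155 symbols, of which 82 were matched to 79 gene models. Another 70 had no gene model of the set in the table, and 3 pointed to several RefSeq genes and were left out. Each list's median was set against 10000 random lists matched on length decile. The random lists were drawn from all 32540 gene models, whereas list members could only come from those paired with a RefSeq gene. How far this difference alone raises or lowers a rank was not examined. The genes named are, per list, up to the 2 with the highest and up to the 3 with the lowest unique share, then the 2 longest gene models and the 2 with most partners among those of at least 1000 bases. Outside this rule, kn1 was named as the founding member of its family. One item is not reported here. Among tied genes the choice was free.

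The lists, the naming rule, the window length and the alternatives were fixed before the data were examined. The alternatives were windows of 25 and 50 bases, the coding strand only, the last 500 bases, other limits for partners and identical copies, and subsets of the gene models. Counting each genomic position once was added after overlapping gene models had been considered as a cause of repeated windows, and a list of auxin genes without 2 uncertain symbols and the vascular genes without cesa11 were added later.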

Results

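The series compared messenger RNA of the L1 and L2 cell layers of the maize shoot apical meristem. The meristem is the dome of stem cells from which the leaves and stem of the shoot arise. L1 is its outermost layer, which forms the epidermis, and L2 is the tissue beneath it. Both layers were taken by laser capture microdissection from 14-day-old seedlings of the inbred line B73. Each layer was represented by 1 sequencing library, so the series held 2 samples in 2 groups of 1 and no replicate. Each library was run on 2 lanes of a Solexa flow cell. Read counts, expression levels and library depths of the 2 layers were not analysed here. No gene is therefore stated to be higher or lower in L1 than in L2, and no p-value for that comparison could be given from 1 library per layer. The data analysed were the sequences of the gene models to which the reads of both layers were aligned. How far short windows of these sequences, introns included, tell the gene models apart was measured for genes of the meristem, of the epidermis and of the tissues next to them.

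The reference held 32540 gene models with 122256597 bases in all. Of these, 30399 carried a GRMZM identifier and 2141 were named after a sequenced clone. They lay on 10 chromosomes, from 2228 gene models on chromosome 10 to 5034 on chromosome 1, and 63 had no known chromosome. The median gene model was 2658 bases long, and the central 90% ran from 638 to 10547 bases. The longest was GRMZM2G326643 on chromosome 1, from position 114842508 to 114917549 on the plus strand, with 75042 bases. The next was GRMZM2G083182, also on chromosome 1, from 244174996 to 244240659, with 65664 bases. Every sequence was as long as its coordinate span, so introns were included and their windows enter all unique shares. Exons alone were not examined. The median GC content was 48.5%, with quartiles of 43.3% and 58.1%.

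Most gene models could be told apart along nearly their whole length, and 20793 (63.9%) had at least 90% unique windows. A window of 32 bases was called unique when it occurred at 1 position of the whole set on either strand. Of 121245666 windows, 82.3% were unique. The median gene model had 95.2% unique windows, with quartiles of 78.3% and 99.6%. In 6229 gene models (19.1%) every window was unique. At the other end, 1366 gene models had no unique window, which is 4.20% of the set (95% Wilson interval 3.99 to 4.42%), and 2162 had under 10%. When gene models that overlap in position were not allowed to cancel each other's windows, these numbers were 497 and 1118. Within the last 500 bases, the part that amplification from the poly(A) tail favours, the median was 100%, and 2389 gene models (7.34%) had no unique window. Of those, 1023 had unique windows farther upstream. This stretch only approximates the 3′ end of the transcript, since it may hold introns. Also, 20.6% of plus-strand and 20.7% of minus-strand sequences ended in a stop codon and may lack the bases after it.

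**Figure D1:**
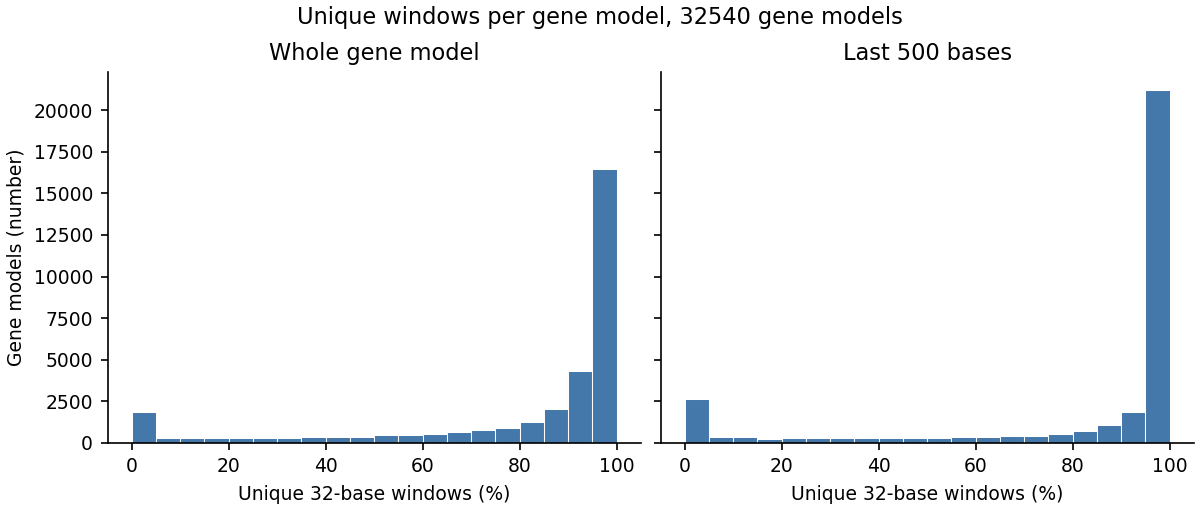
Number of gene models (vertical axis) by the percentage of their 32-base windows that occur at 1 position of the set (horizontal axis, bins of 5 points), over the whole gene model (left) and its last 500 bases (right). Most gene models lie near 100%, with a smaller group near 0% that is larger for the last 500 bases (2389 gene models without a unique window, against 1366).

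The matched gene models of the epidermal and meristem lists had at least 85.9% unique windows each. Among the HD-ZIP IV outer cell layer genes, transcription factors of the epidermis, 4 gene models were matched from 5 symbols and had a median of 99.7% unique windows. Their lowest value was 97.9%, in ocl5 (GRMZM2G130442, chromosome 4, 28833054 to 28839237, minus strand), and their highest 99.8%, in ocl1 (GRMZM2G026643, chromosome 3, 27197008 to 27204698, plus strand). The list stood at the 99.7th percentile of 10000 random lists of the same size matched on length. In the last 500 bases, where ocl5 had 93.6%, the list median was 100% and its rank was the 80.6th percentile. No random list can have a median above 100%, so this lower rank comes from ties at the maximum and is not a loss of uniqueness. The 5 cuticle and wax gene models, matched from a list of 15 symbols, had a median of 99.3%, at the 90.8th percentile. Their lowest value was 96.0%, in gl8b (GRMZM2G087323), which shared 138 windows with AC205703.4_FG007 on chromosome 5. It was 98.5% in gl1 (GRMZM2G114642) and 100% in cr4 (GRMZM2G051637), the receptor kinase CRINKLY4 of epidermal development. The 3 lipid transfer protein genes, from 8 symbols, had a median of 95.9%, at the 48.3rd percentile. Their values were 93.6% in plt1 (GRMZM2G101958), 95.9% in plt2 (GRMZM2G010868) and 100% in ltp3 (GRMZM2G126397). In the last 500 bases these 3 genes were fully unique.

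The 7 class I KNOX genes, matched from 15 symbols, are homeodomain factors that keep the meristem indeterminate. They had a median of 97.9% unique windows and none was below 96.8%. The founding member kn1 (GRMZM2G017087, chromosome 1, 270429924 to 270431507, plus strand) reached 98.7%. The lowest values were 96.8% in lg4a (GRMZM2G094241), 96.9% in lg3 (GRMZM2G087741) and 97.5% in knox4 (GRMZM2G452178), and the highest was 100% in knox3 (GRMZM2G000743). The 11 stem cell and WOX genes, from 19 symbols, had a median of 97.9%, at the 78.8th percentile, and 10 of them had at least 90%. The exception was wus2 (GRMZM2G028622, chromosome 10), a WUSCHEL gene, with 85.9%. It shared 108 windows with wus1 (GRMZM2G047448, chromosome 2), which had 92.5%. Both were 99.8% unique in the last 500 bases. The CLAVATA-type receptor genes fea2 (GRMZM2G104925) and fea3 (GRMZM2G166524) were 100% unique.

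Among the 10 leaf initiation and polarity genes the median was 95.5%, at the 66.4th percentile, and 8 had at least 90%. The 3′ end of one of them was not distinguishable. The gene rld1 (GRMZM2G109987, chromosome 9, 150318075 to 150326340, minus strand), an HD-ZIP III factor of leaf polarity, had 86.0% unique windows overall but 0% in its last 500 bases. That end is overlapped by GRMZM2G110116 on the opposite strand (150316491 to 150319124), with which it shared 1019 windows. Without strand information, reads from this stretch cannot be assigned to 1 of these 2 gene models. The next lowest values were 86.8% in lg2 (GRMZM2G060216) and 90.1% in lbl1 (GRMZM2G020187), and rs2 (GRMZM2G403620), the repressor of KNOX genes in leaves, was 100% unique. The list of auxin genes had 8 members and a median of 95.7%, from 85.8% in GRMZM2G078274 to 100% in spi1 (GRMZM2G025222), an enzyme of auxin synthesis. GRMZM2G078274 and GRMZM2G153233 were paired with the symbols arf3 and arf2, whose products the table of names does not give, so that they belong to this list is not certain. The median was 97.6% without them.

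Among the lists of other tissues, the vascular genes held some members with few or no unique windows. The 4 photosynthesis genes had a median of 94.9%, from 91.9% in ssu1 (GRMZM2G098520), a Rubisco small subunit, to 99.9% in pep1 (GRMZM2G083841), the phosphoenolpyruvate carboxylase of C4 leaves. The 8 vascular gene models had a median of 85.6%, at the 9.56th percentile. Of these, 4 had at least 90%, with 100% in sus1 (GRMZM2G152908) and 99.8% in sh1 (GRMZM2G089713), both sucrose synthase genes, and 3 had under 50%. Among these 3 were the gene models paired with cesa11, a cellulose synthase subunit. GRMZM2G055795 (chromosome 3, 196553351 to 196558979) had 0% unique windows, since all of its 5598 windows occurred in GRMZM2G037413 (chromosome 2, 29786195 to 29792078), which had 4.36%. Without this pair the other 6 gene models had a median of 96.1%, at the 77.8th percentile. The median of all 8 lay midway between members with 76.0% and 95.2%, so the low rank depended on few genes. Leaving out any other symbol was not tried. Also under 50% was the sucrose synthase gene sus2 (GRMZM2G318780), with 43.3%. Of the 19 histone and cytoskeleton gene models, members of multigene families, 3 were paired with the same histone symbols. The list also held an elongation factor gene. The list had a median of 91.1%, at the 10.9th percentile, and 1 member was below 50%. That was his2b5 (GRMZM2G342515, chromosome 4, 160045278 to 160046438), a histone H2B gene with 0% unique windows. All of its 1130 windows occurred in GRMZM2G347412, 41.9 kb away on the same chromosome. The highest values of this list were 99.4% in act1 (GRMZM2G126010) and 98.6% in tub2 (GRMZM2G334899). These percentiles describe the lists and are not a test, since genes are not replicates. With 3 to 19 members each they rest on few genes. The random lists also held gene models without a RefSeq gene, which the lists could not.

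**Figure D2:**
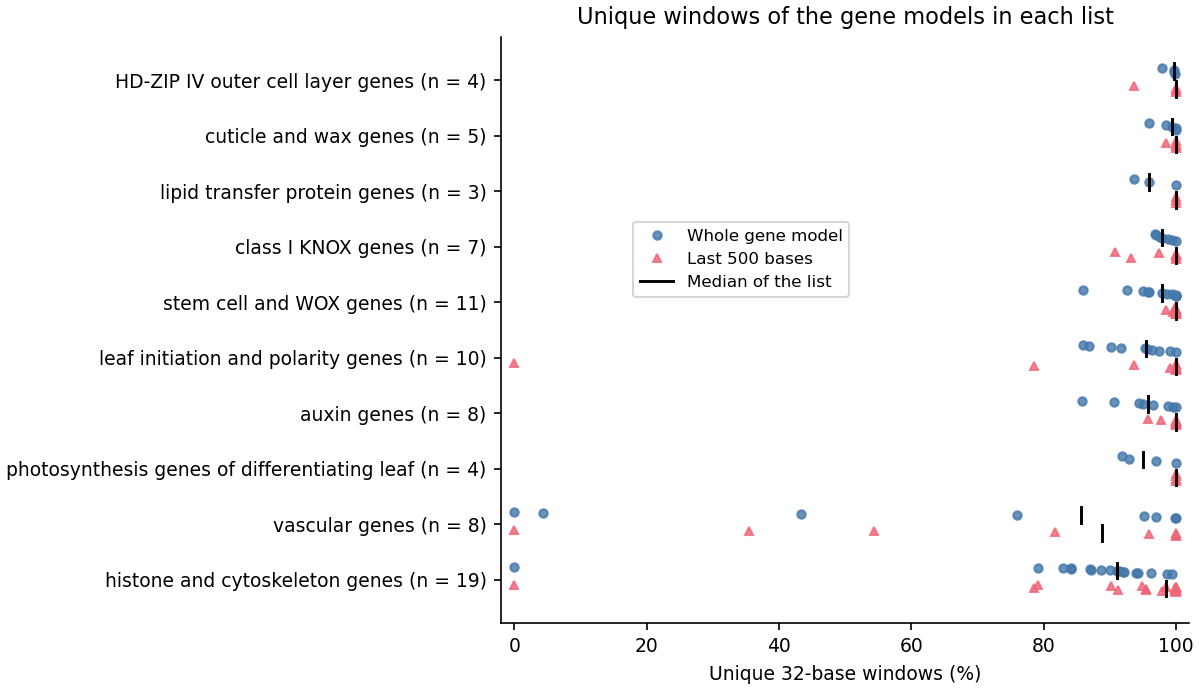
Percentage of unique 32-base windows (horizontal axis) of each gene model in the 10 lists, over the whole gene model (circles) and its last 500 bases (triangles), with the median of each as a black line. Over the whole gene model, all lists lie above 85% except the vascular and the histone and cytoskeleton lists, each with a member at 0%. In the last 500 bases, rld1 of the leaf polarity list is at 0% too.

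About 49.6% of all gene models, 16136, shared at least 100 distinct windows with another. The partner sharing the most windows was on another chromosome for 64.7% of the 16085 gene models with known positions (95% Wilson interval 63.9 to 65.4%), against 89.4% when partners were shuffled. It was on the same chromosome within 200 kb for 27.8% (27.1 to 28.5%), against 0.0361% when shuffled, and 2674 of these partners overlapped the gene model in position. For the other 7.52% it was farther away on the same chromosome. When at least 500 shared windows were required, 46.8% of 7795 closest partners were on another chromosome and 45.2% within 200 kb. The largest numbers of partners among gene models of at least 1000 bases were 240 in GRMZM2G084192 (chromosome 8, 87307860 to 87329257) and 231 in GRMZM2G060349 (chromosome 5, 23207377 to 23237388). Exactly identical sequences were found in 281 gene models, in 139 groups of at most 3.

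Partner genes on different chromosomes were concentrated on a few pairs of chromosomes. After leaving out windows that occurred in more than 5 gene models, 3157 mutual closest pairs joined 2 chromosomes. Chromosomes 2 and 7 held 231 of them against 58.6 expected from random pairing, a ratio of 3.94. Chromosomes 3 and 8 held 288 against 77.7, a ratio of 3.71. The pairs 2 and 10, 4 and 5, and 1 and 9 followed with ratios of 2.95, 2.94 and 2.92. Chromosomes 6 and 8 reached 2.38, 6 and 9 reached 1.96, and 1 and 5 reached 1.96. These 8 of the 45 chromosome pairs lay above 1.72, the highest ratio in 10000 random pairings. The lowest ratio was 0.264, for chromosomes 1 and 8. The meristem genes wus2 and wus1 (chromosomes 10 and 2) lay on a chromosome pair of this group.

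**Figure D3:**
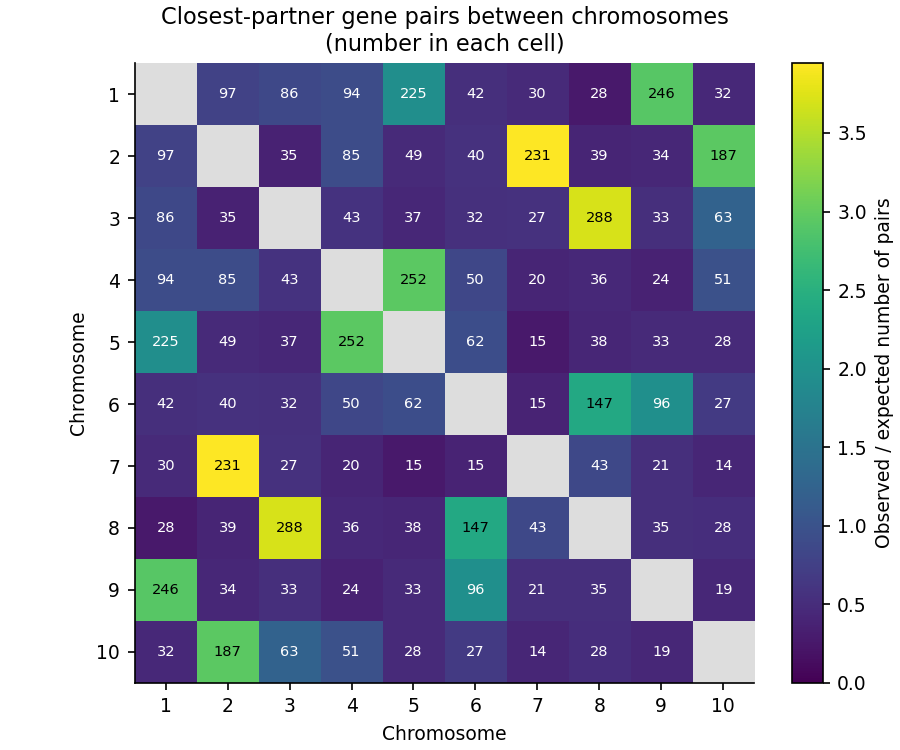
Mutual closest-partner gene pairs between the 10 chromosomes (both axes); the number in each cell counts the pairs and the colour gives the ratio of observed to expected pairs under random pairing, with grey for pairs within a chromosome, which were left out. The brightest cells are chromosomes 2 and 7 (231 pairs) and 3 and 8 (288 pairs).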

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

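Counting each genomic position once and leaving out 2 auxin symbols or cesa11 were chosen after the data had been seen. The other settings were planned. The share of unique windows (82.3%) was 79.4% with windows of 25 bases, 86.3% with 50 bases, 85.6% on the coding strand alone, 82.0% in the last 500 bases and 85.4% with each genomic position counted once. The 1366 gene models without a unique window became 2389 in the last 500 bases, 680 on the coding strand alone and 497 with each genomic position counted once, and the 2162 with under 10% became 1277 on the coding strand and 1118 with each position counted once. Both counts stayed within 1.5 times with windows of 25 or 50 bases. List medians moved beyond their interval in the last 500 bases to 100% (HD-ZIP IV, leaf polarity and photosynthesis genes) and 98.5% (histone and cytoskeleton genes), with 50 bases to 100%, 99.1% and 95.6% (HD-ZIP IV, leaf polarity, histone and cytoskeleton genes) and with 25 bases to 96.1% (KNOX genes). The median length was 2743 bases among gene models of at least 500 bases and 2733 among those with a GRMZM identifier. In 1751 gene models at least 95% of their own windows were found in 1 other gene model, against 281 that were identical. The 1751 include gene models that overlap or lie inside the other, so they are not all separate copies. The share of closest partners within 200 kb (27.8%) was 45.2% from 500 shared windows, 29.5% with windows in at most 5 gene models, and 22.4% within 50 kb. A value counted as moved when a count changed by over 1.5 times, or when a share or median left its own 95% interval. This interval is narrow for values over the whole set. For lists of 3 to 5 members it was the range from the lowest to the highest member, which covers the median with less than 95%. For the KNOX, auxin and vascular lists, with 7 or 8 members, it was the range from lowest to highest too. By this measure 50 alternative values did not move and 24 did. Some of the 50 could not have moved. The interval of the vascular genes ran from 0 to 100%, so even their change from 85.6% to 96.1% without cesa11 counted as not moved. The intervals of the cuticle, lipid transfer, KNOX, stem cell and auxin genes reached 100%, so no rise of these could count. The sequence set has no depth, and no result here depends on one.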

Other observations

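Gene models without a unique window were shorter and richer in GC than the rest, with medians of 1368 against 2740 bases and 54.3% against 48.3% GC. They were more frequent among gene models named after clones (335, or 15.6%) than among those with a GRMZM identifier (1031, or 3.39%), and fell from 11.9% in the shortest length decile to 0.737% in the longest. Chromosomes 1 to 10 differed little, from 3.85% on chromosome 9 to 4.71% on chromosome 2. The gene models of the longest decile were the least unique by median, at 89.5%, while the other deciles lay between 94.2% and 96.8%. Pooled over all windows of a decile the order differed, with 72.0% unique in the shortest decile, 79.2% in the longest and at most 86.0% in between. Within this filtered set, repeats held by many genes were a small part of the shared sequence: 14.8% of all windows occurred in 2 to 5 gene models, 2.37% in 6 to 50 and 0.10% in more.

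Why 1366 gene models had no unique window was tested against 3 explanations, of which the test of neighbouring copies was redefined after the result was seen. Dispersed repeat families held by more than 5 gene models of the set are argued against as the cause for most of them. Only 3.95% of these gene models had most of their windows in more than 5 gene models, although this was above the 0.707% of all gene models. Sequence outside the gene models was not searched, and the set was a filtered one. Repeats with few copies left inside the set are therefore not covered by this test. Near-identical neighbouring copies as the cause for most of them are argued against too: 16.1% shared 95% of their windows with a gene model within 200 kb that did not overlap them, although the share was 80.1% before overlapping gene models were excluded. Overlapping annotation may account for the larger part, since 63.6% (Wilson interval 61.0 to 66.1%) gained a unique window once each genomic position was counted once. Of those that gained, 98.3% lay wholly inside another gene model. For 78.6% of those that gained, every overlapping gene model was on the opposite strand, against 87.5% of all gene models that overlap another. Of the 497 left, 44.1% had a near-identical neighbour and another 53.5% had a near-identical copy only farther away, or on another or an unknown chromosome. The design names no biological group to set against these explanations.

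The concentration of partner genes on 8 chromosome pairs was set against 2 explanations. The number of partner genes per chromosome does not account for it, since no random pairing reached the observed deviation (permutation p = 0.0001, the smallest that 10000 permutations can give). A candidate explanation is that the pairs are remnants of duplicated chromosome segments, as the ancient whole-genome duplication of maize would leave. In that case neighbouring genes have neighbouring partners. Of 3148 neighbours compared, 32.9% had partners on 1 chromosome within 5 Mb of each other. With shuffled partners the mean was 1.15% (permutation p = 0.0001). Shuffling partners only within a chromosome pair gave at most 6.96% in 1000 draws. Duplications of smaller segments at other times stay open.

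The near-identical gene models paired with cesa11 on chromosomes 2 and 3 were 1 example of a wider pattern, chosen after its values were seen. At separate positions, 257 pairs of gene models shared at least 95% of the windows of both, and 115 of these pairs lay on different chromosomes. In 71 pairs both gene models were paired with a RefSeq gene, and in 69 of them (97.2%, Wilson interval 90.3 to 99.2%) this was the same gene. Another 46503 pairs shared at least 100 windows but under 50% of either. In 11899 of them both gene models were paired with a RefSeq gene, and in 27 of these (0.227%) it was the same gene. How the table assigned the identifiers is not given in the sources used here. If it used sequence similarity, near-identical gene models would be paired with the same gene in any case. No conclusion is therefore drawn from these shares.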
